A study of Mus musculus with 6 samples.

How the data were processed

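Whole-genome bisulfite sequencing was analysed for 6 mouse libraries, each a group of its own: embryonic fibroblasts (MEF), induced pluripotent stem cells (iPSC), and 4 sorted populations of cells on the way from one to the other. Bisulfite treatment turns unmethylated cytosines into uracil and leaves methylated ones, so each read reports the state of the CpG sites it crosses. Per the labels, the libraries were made with the Nugen Ovation bisulfite kit from purified genomic DNA. The submitters' processing notes name BSMAP, a bisulfite read aligner, and the genome build mm9, with no version or settings, and read filters, duplicate removal and conversion rates are not given in the sources used here.

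The deposited tables list 1 CpG per line over 2 bp, with the authors' methylated and total calls as a pair of whole numbers and, in a further column, a deposited score. That score equalled 1000 times the ratio of the call counts, rounded down, in every line of the 6 tables, so it was used only to check the call counts. All levels here are percentages computed from the deposited call counts. Coordinates are those of mm9 and are given counted from 1.

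The level of a region is its summed methylated calls over its summed total calls. Autosomal CpGs were used unless X or Y is named. Genome-wide levels used the 7452875 autosomal CpGs with at least 5 calls in all 6 libraries. Tiles of 1 kb were compared between a pair of libraries with a two-sided Fisher's exact test on summed calls, over CpGs with at least 5 calls in both and tiles with at least 3 such CpGs. A tile was called where the Benjamini-Hochberg adjusted p was under 0.05 and the levels differed by at least 20 percentage points. Tiles that fell or rose from MEF to iPSC were also chosen by the same rule on every other CpG. They were then measured on the CpGs left out of the choice, to limit how far chance in the choice enters the measured levels. Neighbouring CpGs share reads, so a part of that chance can remain in the MEF and iPSC levels. The efficient-to-inefficient differences of day 3 and day 6 were compared per tile by a z test on binomial variances, with the same adjustment and size rule. Tiles were named by a rule set before the data were examined: the 5 largest losses and the 5 largest gains of each main comparison among called tiles with at least 10 CpGs.

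With 1 library per group there is no replicate spread. The Fisher tests compare libraries, not conditions, and calls of neighbouring CpGs on 1 read are not independent, so the p-values are too small. The range over the 19 autosomes is given as the only spread; it describes the genome of 1 library and not the variation between animals or sorts. Wilson 95% intervals cover counting error only.

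On simulated calls at the real coverage, independent calls gave 2 false calls among 1084966 tiles for the day 3 pair, and 8.50% of 200 tiles lowered by 30 points and 28.5% of 200 lowered by 40 points were recovered. For the day 6 pair the same simulation gave 11 false calls among 1946113 tiles, with 50.5% of 200 tiles recovered at 30 points and 79.0% of 200 at 40 points. For iPSC against MEF it gave 3 false calls among 1981022 tiles, with 54.0% of 200 recovered at 30 points. The tile differences of the day 3 pair were spread 1.53 times as widely, as a variance, as independent calls would be. With calls spread that widely, the simulation gave 256 false calls for the day 3 pair and 1146 for the day 6 pair. Calls were therefore also tested after dividing them by that factor, a setting chosen after seeing the data, under which the simulation gave 1 and 3 false calls but recovered 4.00% of 200 tiles lowered by 40 points for the day 3 pair and 61.0% for the day 6 pair. A harsher simulation, with 1 draw shared by every 3 calls, gave 76637 false calls for the day 3 pair, far more than the calls made on the data, and was not used further. On independent calls, the z test gave 23 false calls among 1084966 simulated tiles and recovered 27.5% of 200 tiles changed by 40 points at day 6. It was not simulated with more widely spread calls, under which more false calls would arise.

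The alternatives were the coverage minimum, the number of CpGs per tile, the size rule, mean CpG levels in place of summed calls, thinning of every library to the depth of the shallowest, a coverage maximum, centring on the genome-wide difference, tile size, inclusion of X, and the choice and measurement of the tiles that fell or rose. The design and these alternatives were fixed before the data were examined. Centring moved only the size rule, and the adjusted p stayed that of the uncentred test. CpG density is the number of CpG positions of the tables in a 1 kb tile. Tiles called high in 1 end point and low in the other were at 70% or more and at 30% or less, tiles high in both at 80% or more and tiles low in both at 20% or less, chosen and measured on different CpGs. Windows of 100 kb hold at least 100 CpGs in tiles with fewer than 30 CpGs per kb. Isolated low CpGs have at least 8 calls, a level of 5% or less, and a neighbour at 80% or more within 300 bp on both sides. Coverage ratios of X and Y use calls capped at 100 per CpG. Classes of tiles by their level in MEF and iPSC, the densest X tiles, the 100 kb windows, the isolated low CpGs and their comparison at sites covered in all libraries, the levels at called tiles and the day 6 difference within classes of MEF level were chosen after seeing the data. Promoters, gene bodies and lists of genes had been planned, but gene models of mm9 were not used here, so regions are given by position and CpG density and no gene is named.

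Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.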

Results

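The series follows the conversion of mouse embryonic fibroblasts into induced pluripotent stem cells. Fibroblasts were reprogrammed in embryonic stem cell medium supplemented, as labelled, with dox and AA, and intermediates were sorted by surface antigens on days 3 and 6. On both days 1 sorted population is labelled efficient and 1 inefficient. All 4 populations carried SSEA1, an antigen of early embryonic and pluripotent cells. At day 3 the efficient cells were CD73-positive and Sca1-negative and the inefficient cells were CD73-negative and Sca1-positive. At day 6 the efficient cells were EpCAM-positive and Sca1-negative and the inefficient cells were EpCAM-negative and Sca1-positive. EpCAM is an epithelial adhesion molecule. There was 1 library in each of the 6 groups, so no difference below has a replicate check.

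The libraries held 249674720 calls for MEF, 104283268 for day 3 inefficient, 141509568 for day 3 efficient, 196675607 for day 6 inefficient, 462581185 for day 6 efficient and 367811516 for iPSC. The median number of calls per listed CpG ran from 5 in the day 3 inefficient library to 23 in the day 6 efficient library. At least 5 calls were available at 50.03% of autosomal CpGs in the day 3 inefficient library and at 95.1% in the day 6 efficient library. The libraries also differed in where their calls fell. Tiles with 50 or more CpGs per kb had 1.05 and 1.24 times the mean autosomal coverage in the day 3 inefficient and efficient libraries, and 0.684, 0.662, 0.788 and 0.767 times in MEF, day 6 inefficient, day 6 efficient and iPSC.

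Methylation over autosomes was lower in every intermediate than in MEF and highest in iPSC. The level was 69.5% in MEF, 66.9% in day 3 inefficient, 65.0% in day 3 efficient, 65.8% in day 6 inefficient, 62.5% in day 6 efficient and 78.1% in iPSC. These levels weight CpGs by calls, and the day 3 libraries covered CpG-dense tiles, which have low levels, more than the others did. In tiles with fewer than 10, 10 to 29 and 30 or more CpGs per kb, day 3 efficient cells were at 71.0, 71.2 and 15.0%. Day 6 inefficient cells were at 70.3, 70.4 and 16.9% there, so the pooled order of these libraries does not hold within the sparser classes. Wilson 95% intervals, which reflect counting error only, were no wider than 66.885% to 66.909% in the day 3 inefficient library. CpGs at 80% methylation or more made up 49.2% of sites in MEF, 38.0% in day 6 efficient and 69.8% in iPSC. The efficient library was below the inefficient one on 19 of 19 autosomes on both days. The difference was -1.93 points at day 3, with a range over autosomes of -3.01 to -0.984, and -3.31 points at day 6, with a range of -4.44 to -2.72. Over CpGs with at least 10 calls in all libraries these differences were -1.16 and -4.87 points, and as means of CpG levels -1.19 and -2.66.

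**Figure D1:**
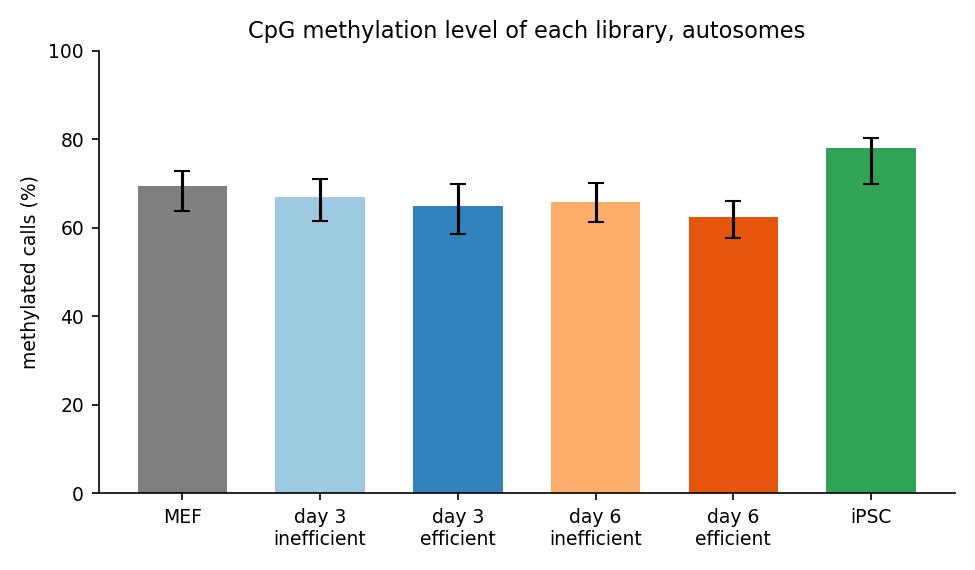
Percentage of methylated calls in each of the 6 libraries over autosomal CpGs with at least 5 calls in all of them. Bars are the pooled levels and the lines span the lowest and highest autosome; the level falls from 69.5% in MEF to 62.5% in day 6 efficient cells and is 78.1% in iPSC.

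The comparison of iPSC with MEF was used as the end points of the conversion. X coverage and the states of single CpGs, described further on, leave open that the iPSC came from other animals. A difference between animals or cell lines and a change on conversion cannot then be told apart. Most of the changed genome gained methylation: 461503 of 1981022 tiles were higher in iPSC and 33535 were lower, by Fisher's exact test with Benjamini-Hochberg adjustment. The median change was 28.1 points among higher tiles and -30.3 points among lower ones. Of tiles with fewer than 10 CpGs per kb, 26.3% were higher and 0.888% lower, and of tiles with 10 to 29, 18.6% were higher and 2.86% lower. In tiles with 30 or more CpGs per kb the balance turned, with 8.23% lower and 4.94% higher. Of the tiles in 100 kb windows with a MEF level under 60%, 38.4% were higher, against 7.66% in windows at 80% or more, which averaged 82.9% in MEF and so had little room for a rise of 20 points. The level of these windows varied less in iPSC, with an SD over windows of 5.46 points against 6.29 in MEF. Their mean was 83.8% in iPSC and 73.7% in MEF, so less room above the mean may narrow the spread in iPSC. After centring the size rule, but not the test, on the genome-wide difference of 9.02 points, 63518 tiles were lower and 210918 higher. Lower tiles were then 23.1% of calls instead of 6.77%.

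Some tiles were nearly fully methylated in MEF and nearly unmethylated in iPSC, or the reverse. The largest loss was on chromosome 8 from 44391001 to 44392000, where 14 shared CpGs were at 94.5% in MEF (Wilson interval 89.1 to 97.3%, 127 calls) and 2.84% in iPSC (1.44 to 5.50%, 282 calls), with an adjusted p of 2.155e-80 by Fisher's exact test. The other 4 largest losses were on chromosome 8 from 83383001, chromosome 7 from 111405001, chromosome 3 from 41360001 and chromosome 5 from 53947001, with differences of -91.6, -87.8, -87.1 and -86.8 points. All of these 5 tiles were at 82.1% or more in the 4 intermediates. The largest gain was on chromosome 5 from 131099001 to 131100000, from 2.36% in MEF (0.807 to 6.71%, 127 calls) to 96.1% in iPSC (92.1 to 98.1%, 178 calls), with an adjusted p of 3.771e-69 by Fisher's exact test. Gains of 90.3, 89.6, 89.4 and 89.2 points followed on chromosome 4 from 154508001, chromosome 1 from 164148001, chromosome 9 from 32631001 and chromosome 9 from 117159001. In the intermediates the 5 gained tiles stayed at 22.2% or less.

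The X chromosome differed from the autosomes. X coverage was 0.477 of autosomal coverage in iPSC and 0.877 to 0.973 in the other libraries. The 300 X tiles with 50 or more CpGs per kb were at 26.1% in MEF, between 24.5% and 26.2% in the 4 intermediates and at 7.93% in iPSC. Autosomal tiles of that density were at 5.54% in MEF and 5.47% in iPSC. Of 163 dense X tiles at 20 to 60% in MEF, 128 were under 10% in iPSC. X tiles with fewer than 10 CpGs per kb went the opposite way, from 67.8% in MEF to 83.9% in iPSC. Autosomal tiles of that density also rose, from 74.5% in MEF to 85.5% in iPSC.

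**Figure D2:**
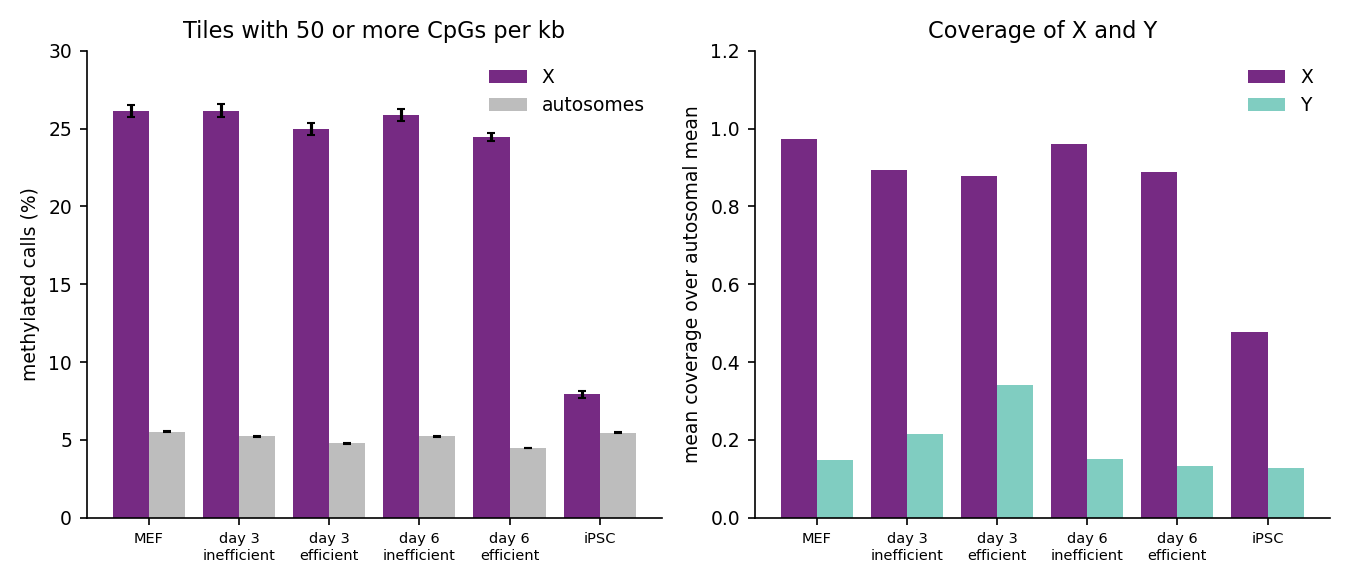
Left, percentage of methylated calls in tiles with 50 or more CpGs per kb on X and on autosomes in each library, with Wilson 95% intervals. Right, mean coverage of X and Y CpGs over the autosomal mean; in iPSC X coverage is 0.477 and the dense X tiles are at 7.93%, against 26.1% in MEF.

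At day 3 the efficient library was compared with the inefficient one, which asks whether methylation differs between cells sorted for a different prospect of reprogramming. Few single tiles differed: 612 of 1084966 were lower in efficient cells and 207 were higher by Fisher's exact test with adjustment. The 604 lower tiles covered in all libraries averaged 76.8% in day 3 inefficient and 40.4% in day 3 efficient cells. In libraries that took no part in choosing them they were at 66.1% in MEF, 53.8% in day 6 inefficient, 47.3% in day 6 efficient and 75.6% in iPSC. On chromosome 11 from 11926001 to 11927000, 41 CpGs were at 71.2% in inefficient cells (65.4 to 76.3%, 260 calls) and 28.6% in efficient cells (24.0 to 33.7%, 332 calls), with an adjusted p of 1.824e-19. The other 4 largest losses, on chromosome 15 from 8241001, chromosome 3 from 30005001, chromosome 18 from 75692001 and chromosome 5 from 118500001, ran from -42.7 to -42.1 points. The 5 largest gains were on chromosome 2 from 84884001, chromosome 11 from 36346001, chromosome 13 from 38681001, chromosome 19 from 55842001 and chromosome 17 from 86217001, with differences of 35.9 to 37.3 points. With calls divided by the variance inflation of this pair, 15 lower tiles and 1 higher tile remained. With at least 10 calls per CpG there were 71 and 21.

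At day 6 losses in 1 kb tiles of the efficient library were nearly one-sided. Of 1946113 tiles, 9462 were lower in efficient than in inefficient cells and 462 were higher. With calls spread as widely as those of the day 3 pair, the simulation gave 1146 false calls in both directions together. An unknown and possibly large part of the higher tiles may therefore be false. The counts on the data exceed those of day 3, but not under every setting. In 5 kb tiles there were 207 lower and 19 higher at day 6 against 450 and 114 at day 3, and after thinning to the same total number of calls there were also fewer at day 6. The median difference of the lower tiles was -24.2 points. Of the 7051 lower tiles covered in all libraries, 4551 (64.5%) were at 60% or more in both MEF and iPSC, below the 79.0% of all 1040021 such tiles, and 571 were at 30% or less in iPSC, a state of 3.50% of all. These tiles averaged 75.9% in MEF, 66.1% in day 3 efficient, 67.5% in day 6 inefficient, 42.9% in day 6 efficient and 69.4% in iPSC. At the same time, losses at day 6 and losses from MEF to iPSC met more often than independent lists would: 2025 of 9440 tiles lower at day 6 were also lower in iPSC than in MEF, against 161 for independent lists, and these comparisons share no library. Day 6 losses met tiles higher in iPSC 982 times, against 2195. Of 458 tiles higher in day 6 efficient cells, 212 were also higher in iPSC than in MEF, against 106.5. The expected numbers allow neither for CpG density nor for the level in MEF, on which a rise depends. Of 122211 tiles at 40 to 60% in MEF, 95801 were higher in iPSC by 20 points or more. At 60 to 80% this held for 91860 of 371062. The 217 higher day 6 tiles covered in all libraries averaged 59.0% in MEF, so their excess was not separated from their starting level.

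The tile on chromosome 13 from 96593001 to 96594000 fell only in the day 6 efficient library among the 6. It was at 67.2% in MEF, 73.3% in day 6 inefficient (64.6 to 80.5%, 116 calls), 24.7% in day 6 efficient (19.7 to 30.5%, 243 calls) and 69.4% in iPSC, with an adjusted p of 5.09e-14 for the day 6 pair by Fisher's exact test. On chromosome 15 from 102987001 the level was 73.1% in inefficient and 23.7% in efficient cells, and stayed at 35.2% in iPSC. The other 3 largest losses, on chromosome 10 from 80774001, chromosome 17 from 88259001 and chromosome 17 from 5204001, were -49.0, -47.4 and -46.9 points. The largest gain was 33.5 points on chromosome 14 from 67445001. Gains of 29.8, 29.2, 27.3 and 27.0 points were found on chromosome 11 from 20209001, chromosome 7 from 74387001, chromosome 11 from 9994001 and chromosome 1 from 190292001. With every library thinned to the same total number of calls, 191 of 1083830 tiles were lower and 2 higher at day 6, and 207 of 837126 were lower and 59 higher at day 3. Coverage per tile still differed between the days after thinning. With calls divided by the variance inflation, 2941 lower and 31 higher tiles remained at day 6.

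Each intermediate was compared with MEF to place it between the MEF and iPSC libraries. The shares below take iPSC as the end point, although it may come from other animals. Tiles lower than in MEF numbered 13457 in day 3 inefficient, 28139 in day 3 efficient, 52377 in day 6 inefficient and 126127 in day 6 efficient. Tiles higher than in MEF numbered 1352, 1018, 2660 and 3370. With the size rule centred on the genome-wide difference, lower tiles numbered 12623, 22313, 40682 and 64700 and higher tiles 1526, 1452, 4067 and 8464. At equal total depth the lower tiles kept that order, at 3670, 5456, 10392 and 29133. The 12548 tiles that fell from MEF to iPSC were at 76.4% in MEF, 70.9% in day 3 inefficient, 68.5% in day 3 efficient, 64.9% in day 6 inefficient, 57.2% in day 6 efficient and 45.7% in iPSC. Day 6 efficient cells had covered 62.7% of the loss, with a range over autosomes of 56.5 to 67.9%, and day 3 inefficient cells 18.1%, with a range of 14.3 to 22.9%. The 69065 tiles that rose from MEF to iPSC, from 54.9% to 83.9%, were at 51.4% in day 6 efficient cells and so below MEF.

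Tiles in neither set also fell, from 73.9% in MEF to 66.9% in day 6 efficient cells. Measured relative to them, day 6 efficient cells had covered 34.6% of the loss and 14.4% of the gain, so the direction at the rising tiles depends on this reference. The 1135 tiles high in MEF and low in iPSC averaged 79.7% in MEF, 63.3% in day 6 inefficient, 53.3% in day 6 efficient and 23.7% in iPSC, and 23.3% of them were at 30% or less in day 6 efficient cells. The 5378 tiles low in MEF and high in iPSC were at 26.5% in MEF, 28.9% in day 6 efficient and 84.2% in iPSC. The 156365 tiles high in both fell from 85.7% in MEF to 79.2% in day 6 efficient cells and were at 89.1% in iPSC.

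**Figure D3:**
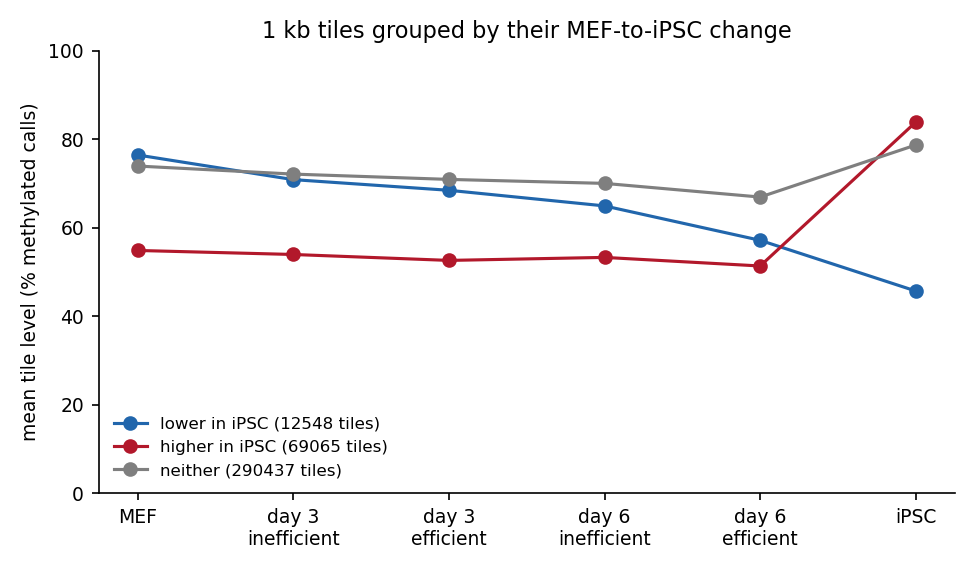
Mean level of 1 kb tiles in each library for tiles that fell, rose or did neither from MEF to iPSC, chosen and measured on different CpGs. Tiles that fell pass through 57.2% in day 6 efficient cells on the way from 76.4% to 45.7%, while tiles that rose are at 51.4% there and 83.9% in iPSC.

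The efficient-to-inefficient difference at day 6 varied with the change from MEF to iPSC. It was -7.78 points at tiles that fell, -3.09 at tiles in neither set and -1.94 at tiles that rose, each below 0 on 19 of 19 autosomes. At day 3 the corresponding values were -2.41, -1.21 and -1.34 points. Over bins of the MEF-to-iPSC change, the day 6 difference ran from -9.70 points at tiles that fell by more than 40 points to -0.887 at tiles that rose by more than 40. The day 6 difference also depended on the level in MEF, from -0.637 points at tiles under 20% to -2.99 at 80% or more, and tiles that rise start low. Among tiles at 40 to 60% in MEF it was -7.91 points where iPSC was lower by 20 points or more, -4.08 where the change was smaller and -2.10 where iPSC was higher by 20 or more. Among tiles at 60 to 80% in MEF these values were -8.68, -2.99 and -2.04. Tested per tile, the difference was more negative at day 6 than at day 3 in 2168 of 1049760 tiles and more positive in 756. These counts were not corrected for the wider spread of the calls, so an unknown part of them is false. With at least 10 calls per CpG these counts were 68 and 22 of 34695 tiles. Of 611 tiles lower in efficient cells at day 3, 35 were also lower at day 6, against 4.11 for independent lists, and 2 were higher at day 6, against 0.127. Calls on both days depended on CpG density, for which these expected numbers do not allow. The opposite pair exceeded its expected number by a larger factor, 15.7 from 2 tiles against 8.51. The excess therefore does not show that losses recur. No tile was higher on both days, against 0.0427, a number too small for the absence to say anything about gains. Of these 611 tiles, 47 were lower in iPSC than in MEF, against 13.7, and 175 were higher, against 124, again without allowance for the level in MEF.

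**Figure D4:**
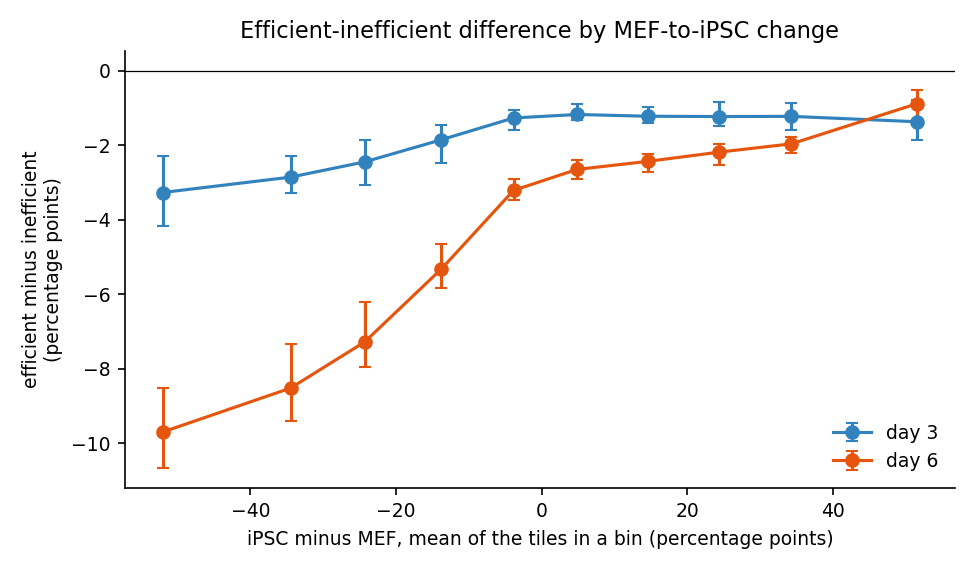
Efficient minus inefficient level in percentage points at day 3 and day 6, against the mean iPSC minus MEF difference of the tiles in each bin. Lines through the points span the lowest and highest autosome; the day 6 difference runs from -9.70 to -0.887 points and the day 3 difference from -3.27 to -1.37 points between the outermost bins.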

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

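All tests of explanations in this part were chosen after the results were seen.

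At 12 named tiles the efficient-to-inefficient difference passed the z test on binomial variances between the 2 days. Among the losses of day 3, the day 6 difference was above the day 3 difference by 52.6 points on chromosome 3 from 30005001, 28.9 on chromosome 18 from 75692001 and 63.0 on chromosome 5 from 118500001. At the 5 gains of day 3, efficient cells were not higher at day 6, and the day 6 minus day 3 value was -38.3 points on chromosome 2 from 84884001, -49.2 on chromosome 11 from 36346001, -41.6 on chromosome 13 from 38681001, -41.2 on chromosome 19 from 55842001 and -43.6 on chromosome 17 from 86217001. Among the losses of day 6 it was -65.7 points on chromosome 15 from 102987001, -49.4 on chromosome 10 from 80774001, -53.3 on chromosome 13 from 96593001 and -50.1 on chromosome 17 from 5204001. These tiles were picked for a large difference on 1 of the days compared, which inflates that day's value, so the test does not show by itself that the days differ.

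Y coverage over autosomal coverage was above that of MEF, 0.149, in 3 libraries. It was 0.217 in day 3 inefficient, 0.341 in day 3 efficient and 0.151 in day 6 inefficient, the last close to MEF. Both day 3 libraries also had the highest coverage of tiles with 50 or more CpGs per kb, at 1.05 and 1.24 times the autosomal mean. Coverage bias and the sex of the cells therefore cannot be told apart from these ratios.

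The lower level of day 6 efficient than of day 6 inefficient cells, largest at tiles that fall from MEF to iPSC, was set against 3 explanations. A line was fitted through the difference against the log2 ratio of efficient to inefficient calls over all 12548 tiles. At equal calls it gave -5.45 points, with a standard error of 0.340 over autosomes and a range of -9.07 to -2.89. If the line holds there, the value argues against depth as the only cause. The slope of -1.76 points per log2 unit leaves a part open. Few tiles have near-equal calls, so the line is read at the edge of the data, and autosomes of the same libraries are not replicates. At the 36 tiles with near-equal calls (ratio 1.13, against 2.48 over all) the difference was -6.62 points with a standard error of 1.45 over tiles, short of the limit set for that test. The extra difference over tiles in neither set was -5.51, -4.95 and -3.40 points in the 3 classes of CpG density from sparse to dense. These values argue against coverage bias by density. As the only cause, an admixture of cells with the iPSC profile would need a share of 40.4%. Such a share would raise the rising tiles by 12.4 points, where the difference was -1.94 points. A smaller admixture together with a loss over all tiles was not tested and stays open. A loss that goes with the efficient state may account for the -7.78 points as an untested hypothesis, but each population is 1 library, so another difference between libraries stays open.

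In iPSC, X coverage near 0.477 of the autosomes came with dense X tiles at 7.93%. Coverage bias against X is argued against by the day 6 efficient library, which has nearly the same coverage by CpG density and an X ratio of 0.888. Cells with 1 X and 1 Y are argued against by the Y ratio of 0.127, the lowest of the 6 libraries. A candidate explanation is a line that holds 1 X and no methylated inactive copy, which was not tested further and would make the X comparison one of cell lines. X was left out of the tile counts.

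Single CpGs near 0 in MEF between methylated neighbours differed in iPSC: of 5616 such sites covered in iPSC, 13.9% were at 70% or more there, against at most 0.464% in the intermediates. At the 129 of these sites with enough calls in all libraries, the shares were 25.6% in iPSC and at most 1.55% in the intermediates. Neighbouring sites shared their state in 94.2% of pairs, against at most 79.0% in 10000 shuffles within chromosomes (one-sided permutation p = 0.0001, the smallest these can give), as blocks of sequence difference between the iPSC and the other animals would predict, so a mixed strain background may account for them. At sites low in iPSC, 10.3% were at 70% or more in MEF, 12.1 to 16.3% in the day 3 and day 6 inefficient and day 3 efficient libraries and 4.58% in day 6 efficient cells, but each library covers other sites; at the 261 with enough calls in all libraries the shares ran from 22.2% in day 6 efficient to 30.3% in MEF. Without their most changed CpG, 60.8% of tiles called higher in iPSC and 75.6% of tiles called lower kept a mean difference of 20 points or more, which leaves open how much single polymorphic CpGs add to either count. For the remaining tiles, and for tiles with several such sites, a sequence difference and a methylation change cannot be told apart without the animals' sequence.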

How the results depend on the processing

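Dividing calls by the variance inflation, the further rules on the median CpG and on the most changed CpG, and measuring relative to tiles in neither set were chosen after seeing the data; all other settings were planned. Genome-wide, iPSC above MEF, every intermediate below MEF and efficient below inefficient on both days held under every setting run, as did the direction of the loss at tiles that fall from MEF to iPSC. The order of day 6 inefficient and day 3 efficient cells did not. For the named tiles, 102 of 103 alternative values kept their direction and 20 points, 1 kept its direction only, and 0 reversed. Named tiles without a value under an alternative are not in these counts. With at least 10 calls per CpG, only 2 named day 3 tiles had a value. These were chromosome 18 from 75692001, at -34.7 points, and chromosome 17 from 86217001, at 45.6 points. The tiles were chosen as extremes of largely the same calls, so these counts do not test chance in the choice. The planned promoter, gene body and gene list results were not run because gene models of mm9 were not used here, and no paired analysis was possible because each group has 1 library. The causes of the changes in count were not tested.

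With at least 3 calls per CpG, called tiles were 1349 lower and 468 higher for day 3 efficient against inefficient. With at least 10 calls per CpG, called tiles were 71 lower and 21 higher for day 3 efficient against inefficient, 285 higher for day 6 efficient against inefficient, and 1988 lower and 258 higher for day 3 inefficient against MEF. That minimum gave a further 8498 lower and 370 higher for day 3 efficient against MEF. With a size rule of 10 points, called tiles were 67525 lower and 785268 higher for iPSC against MEF, 20422 lower and 958 higher for day 6 efficient against inefficient, and 1621 higher for day 3 efficient against MEF. The 10-point rule gave a further 5154 higher for day 6 inefficient against MEF, and 256452 lower and 10530 higher for day 6 efficient against MEF. With a size rule of 30 points, called tiles were 17091 lower and 191908 higher for iPSC against MEF, 1567 lower and 132 higher for day 6 efficient against inefficient, and 580 higher for day 3 inefficient against MEF. The 30-point rule gave a further 16041 lower and 313 higher for day 3 efficient against MEF, 24861 lower and 500 higher for day 6 inefficient against MEF, and 47081 lower and 532 higher for day 6 efficient against MEF. With all libraries thinned to the same total number of calls, called tiles were 15773 lower and 128516 higher for iPSC against MEF, 207 lower and 59 higher for day 3 efficient against inefficient, and 191 lower and 2 higher for day 6 efficient against inefficient. Thinning gave a further 3670 lower and 275 higher for day 3 inefficient against MEF, 5456 lower and 106 higher for day 3 efficient against MEF, and 10392 lower and 332 higher for day 6 inefficient against MEF. Finally, thinning gave 29133 lower and 760 higher for day 6 efficient against MEF. Centred on the genome-wide difference, called tiles were 63518 lower and 210918 higher for iPSC against MEF, 5814 lower for day 6 efficient against inefficient, and 4067 higher for day 6 inefficient against MEF. Centring gave a further 64700 lower and 8464 higher for day 6 efficient against MEF. In 500 bp tiles, called tiles were 60675 lower for iPSC against MEF, 721 higher for day 6 efficient against inefficient, and 4755 higher for day 6 inefficient against MEF. The smaller tiles gave a further 190898 lower and 8819 higher for day 6 efficient against MEF. In 5 kb tiles, called tiles were 3472 lower and 94803 higher for iPSC against MEF, 450 lower and 114 higher for day 3 efficient against inefficient, and 207 lower and 19 higher for day 6 efficient against inefficient. The larger tiles gave a further 2837 lower and 195 higher for day 3 inefficient against MEF, 3967 lower and 75 higher for day 3 efficient against MEF, and 4152 lower and 24 higher for day 6 inefficient against MEF. Finally, the larger tiles gave 9219 lower and 31 higher for day 6 efficient against MEF. With a median CpG difference of 20 points as a further rule, called tiles were 5913 lower and 298 higher for day 6 efficient against inefficient, 642 higher for day 3 efficient against MEF, and 1599 higher for day 6 inefficient against MEF. The median rule gave a further 2049 higher for day 6 efficient against MEF. With 20 points kept without the most changed CpG, called tiles were 280530 higher for iPSC against MEF, 4324 lower and 180 higher for day 6 efficient against inefficient, and 833 higher for day 3 inefficient against MEF. Leaving out that CpG gave a further 464 higher for day 3 efficient against MEF, 33775 lower and 1038 higher for day 6 inefficient against MEF, and 72740 lower and 1237 higher for day 6 efficient against MEF. With calls divided by the variance inflation of the day 3 pair, called tiles were 15 lower and 1 higher for day 3 efficient against inefficient, 2941 lower and 31 higher for day 6 efficient against inefficient, and 4180 lower and 98 higher for day 3 inefficient against MEF. The division gave a further 11456 lower and 99 higher for day 3 efficient against MEF, 28539 lower and 841 higher for day 6 inefficient against MEF, and 2059 higher for day 6 efficient against MEF.

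The share of the loss from MEF to iPSC reached was 19.2% in day 3 inefficient, 26.6% in day 3 efficient and 61.0% in day 6 efficient cells when tiles were chosen and measured on all CpGs. With a 40-point rule it was 15.4, 21.3, 30.7 and 50.3% in day 3 inefficient, day 3 efficient, day 6 inefficient and day 6 efficient cells. Relative to tiles in neither set it was 10.6, 13.9, 21.4 and 34.6% in the same order. The share of the gain reached, near or below 0 as reported, was 1.22, -2.93, -0.566 and -6.31% on all CpGs, -0.399, -3.39, 1.53 and -0.397% with the 40-point rule, and 3.70, 3.17, 9.66 and 14.4% relative to tiles in neither set, so its sign depends on the setting. With the CpG sets for choice and measurement exchanged it was -12.5% in day 6 efficient cells.

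Genome-wide levels in the order MEF, day 3 inefficient, day 3 efficient, day 6 inefficient, day 6 efficient and iPSC were 69.9, 69.3, 68.1, 68.4, 63.5 and 75.3% over the 386216 CpGs with at least 10 calls in all libraries. They were 69.5, 66.4, 64.3, 65.9, 62.7 and 78.5% over every CpG a library covers, and 68.7, 66.7, 65.5, 64.8, 62.1 and 77.8% as means of CpG levels. In the same order of settings, iPSC minus MEF was 5.41, 8.94 and 9.13 points, day 3 efficient minus inefficient was -1.16, -2.14 and -1.19 points, and day 6 efficient minus inefficient was -4.87, -3.25 and -2.66 points. Over these settings, day 6 inefficient cells were above day 3 efficient cells except as means of CpG levels. They were also below them in tiles with fewer than 10 and with 10 to 29 CpGs per kb, at 70.3 against 71.0% and 70.4 against 71.2%. With at least 10 calls per CpG, 68 tiles had a more negative and 22 a more positive efficient-to-inefficient difference at day 6 than at day 3.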

Other observations

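CpG-dense autosomal tiles at intermediate methylation in MEF were more often still in that state in each of the 4 intermediates than in iPSC. Of 7955 tiles with 50 or more CpGs per kb and at least 20 of them covered in all libraries, 131 were at 30 to 70% in MEF. Of these, 100 were still in that range in day 3 inefficient, 87 in day 3 efficient, 102 in day 6 inefficient and 90 in day 6 efficient cells. In iPSC 47 were in the range, 82 were under 30% and the mean level was 26.5%, against 44.2% in MEF. The class was chosen after seeing the data, and choosing on the MEF level alone removes some tiles by chance. Among the 102 that were in the range in both MEF and day 6 inefficient cells, 84 were in it in day 6 efficient cells and 39 in iPSC.

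Tiles low in both MEF and iPSC, 20637 with a median of 50 CpGs per kb, stayed low throughout. Their mean was 4.41% in MEF, 2.91% in day 6 efficient cells and 5.99% in iPSC.

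Levels in 100 kb windows were lower in day 6 efficient cells than in MEF in each class of MEF level. Windows in the 4 classes of MEF level went from 54.8 to 49.5%, 66.7 to 60.5%, 74.8 to 67.9% and 82.9 to 75.5%. In iPSC they were at 73.2, 82.9, 84.2 and 85.4% in the same order. The classes were made on the MEF level from which the fall is measured, so its size cannot be compared between them.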
